A study of Mus musculus with 9 samples.

How the data were processed

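Lung total RNA from 9 samples of FVB/N mice was labelled with biotin and hybridised to Affymetrix mouse 430A arrays, per the labels. Groups were taken from the sample titles: WT, HE (1 transgenic allele) and HO (2 transgenic alleles), with 3 arrays each. HO replicate 2 is titled homozygous and its genotype field gives 2 alleles, but its description writes the genotype with 1; it was kept as HO, and counted as HE in an alternative chosen after seeing the data. The labels call the samples triplicate without saying that each came from a separate animal, so p-values measure the spread between these samples, which could be partly technical.

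The deposited table holds 1 linear intensity per probe set and array, for 22690 probe sets. From the values, the authors scaled every array to the same mean after leaving out the lowest and highest 2% of values, 1500 on each array. The software that summarised probes to probe sets is not given in the sources used here, and no detection calls were used. The share of values at or under the floor described next ran from 4.29% to 5.53% per array. The ratio of 3' to 5' control probe sets ran from 1.07 to 1.39 for Actb and from 0.768 to 0.886 for Gapdh. No 2 arrays were copies: the smallest median absolute log2 difference between arrays was 0.145. Arrays give no count depth, so their number and the signal above background set the precision.

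Intensities were raised to a floor at the 5th percentile of all values (25.5) and converted to log2, keeping the deposited scaling. The 64 control probe sets were left out, and probe sets with a mean log2 under the 40th percentile (8.90) were removed, which left 13576. Group means were fitted to all 9 arrays at once with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which leaves 6 residual degrees of freedom before moderation. The contrasts were HO minus WT, HE minus WT, HO minus HE and the mean of both transgenic groups minus WT, with a moderated F test over the 3 groups. Benjamini-Hochberg adjustment ran over the 13576 probe sets with a threshold of 0.05. Values are log2 differences with moderated standard errors.

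Gene symbols came from the platform's probe annotation: 20380 probe sets had 1 symbol, 691 several and 1555 none, and probe sets with several were not named. Of those with 1 symbol, 20351 matched a RefSeq gene table of assembly GRCm38.p6 by gene identifier and 0 symbols were changed. That table was otherwise used only for which genes neighbour each other. Of 40 gene lists fixed beforehand, covering lung cell types, stress, inflammatory and metabolic pathways and CFTR biology, 36 had at least 5 measured genes. They were tested on 8184 genes, each at its probe set of highest mean, with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry.

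Named genes followed a rule. For each comparison with WT the rule took the genes of largest change past the threshold whose groups did not overlap, filled to 10 in each direction by lowest p where fewer passed. For HO against HE it took 5 in each direction. It added up to 4 members of lowest p from each list described, and Cftr and Sftpc. Because no probe set passed, all named genes come from the filling step, the lists or the fixed pair, and other probe sets are given for the leading genes described, and for a list member where they were nearer 0 by over 0.3 or of opposite sign. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

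The alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, no floor, a floor at the 20th percentile, the replicate number as a block, a trended and robust eBayes, array weights, a fit of only the arrays compared, 1 probe set per gene, and each array left out in turn. The replicate numbers in the titles also part the source names into 3 sets. They paired HO with WT by the fixed criterion, since deviations from the group means correlated at 0.19, 0.14 and 0.28 across probe sets for numbers 1, 2 and 3. Each number holds 1 array of each group, so 1 number alone gives no spread within a group, and the number entered the fit as a block. The shared WT arrays were allowed for with 100 simulations of unchanged groups, and, chosen after seeing the data, with 100 of the 108 relabellings of arrays within replicate numbers (the mirror of HO and HE counted once).

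The same functions were tested on simulated data drawn from the real means and moderated variances of the 13576 probe sets, with 200 changed, over 10 runs. Moderation evens out the variances between probe sets, so the shares called may differ from those at the unmoderated spreads. For HO against WT, 10.8% of probe sets changed by 0.5 on the log2 scale were called, 88.2% of those changed by 1 and 98.4% of those changed by 1.5, with 7.4 false calls per run. For both transgenic groups against WT the shares were 22.4%, 96.2% and 99.8%. A list shifted by 0.5 was called in 10 of 10 runs of either comparison. The simulated probe sets were drawn independently, with no correlation between genes and no effect of replicate number. In the real data the lists called had estimated correlations of 0.262 to 0.546, so the runs do not show how reliable a list call is. The shares of probe sets called hold for 200 changed ones and would be lower with fewer. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.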

Results

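Messenger RNA levels were measured in lung RNA of adult FVB/N mice that carried a human CFTR cDNA. It was driven by the promoter of surfactant protein C, a gene of alveolar epithelial cells. CFTR is the epithelial chloride and bicarbonate channel that is mutated in cystic fibrosis, and the mice kept both copies of their own Cftr gene. The series asks how extra normal human CFTR affects the lung. There were 9 Affymetrix arrays in 3 groups of 3: wild type (WT), mice with 1 transgenic allele (HE) and mice with 2 transgenic alleles (HO). The arrays were alike in overall signal, with medians between 697 and 742, and the number of arrays limits the precision of every comparison. The mean correlation between arrays was 0.966 within groups and 0.968 between groups. For a typical probe set the standard error of a difference between 2 groups was 0.16 on the log2 scale. The 95% interval reached 0.35 to either side. Both come from the fit without the replicate number, so they include the spread between replicate numbers.

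Sftpc, the surfactant protein C gene of the mouse, and the mouse's own Cftr showed no detectable difference. Sftpc, at a log2 signal of 15.91 ± 0.25 in WT (SD, n = 3), differed from WT by 0.03 ± 0.15 (SE) in HO and by -0.04 ± 0.15 in HE. Mouse Cftr, at 9.98 ± 0.22 in WT, differed by 0.03 ± 0.14 in HO and by 0.04 ± 0.14 in HE. The 95% intervals for HO minus WT were -0.31 to 0.37 for Sftpc and -0.28 to 0.34 for Cftr. The Sftpc probe set was among the 4 highest of every array, and saturation of so strong a signal, which would make a difference look smaller, was not tested. These probe sets were designed for mouse transcripts. Whether the Cftr probe set also binds the human transcript was not tested, so its values are not a check of the transgene or of the genotype labels.

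The first comparison asked what 2 transgenic alleles did to lung RNA. No probe set of the 13576 tested passed an adjusted p of 0.05 with limma (lowest adjusted p = 0.602), against 610 at an unadjusted p under 0.05 and 679 at that level by chance. Of these 610, 229 were higher and 381 lower in HO, a balance that depends on the scaling: it was 287 and 289 with quantile normalization and 428 and 211 with median centring. The values at the top of the ranking are therefore given as values only. Thsd1, a membrane protein with a thrombospondin domain, was at 1.96 times its WT signal in HO, a log2 difference of 0.97 ± 0.16 (SE, n = 3 per group), with all 3 HO arrays above all 3 WT arrays. Its other probe set gave 1.06. Fkbp5, a co-chaperone of steroid hormone receptors, had a log2 difference of 0.83 ± 0.16 in HO, but 0.16 at its other probe set. Rpl37a, a ribosomal protein gene, had 1.497 ± 0.28 at 1 probe set and 0.16 and 0.22 at the others. At the lower end stood Sdhd, a subunit of succinate dehydrogenase (-0.85 ± 0.17, other probe set 0.05), the actin-binding Tagln2 (-0.71 ± 0.14, other -0.29), Eipr1 (-0.77 ± 0.15) and the iron exporter Slc40a1 (-0.73 ± 0.16, other -0.27). Srxn1, which repairs oxidised peroxiredoxins, was at -1.15 ± 0.25 by 1 probe set and at -0.03 and 0.07 by the others. Of the 20 leading genes, 13 had another measured probe set, and in 1 of these 13, Thsd1, another probe set had an unadjusted p under 0.05 in the same direction. The HO and WT arrays did not overlap for 1205 probe sets (8.88%), where chance gives 10%. The 10% and the 679 leave aside the replicate number, which parted the arrays more than genotype did. In a 2-group fit of both transgenic groups against WT, 600 probe sets had an unadjusted p under 0.05. With the number as a block it was 814, so a count under 679 does not show less difference than chance.

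**Figure D1:**
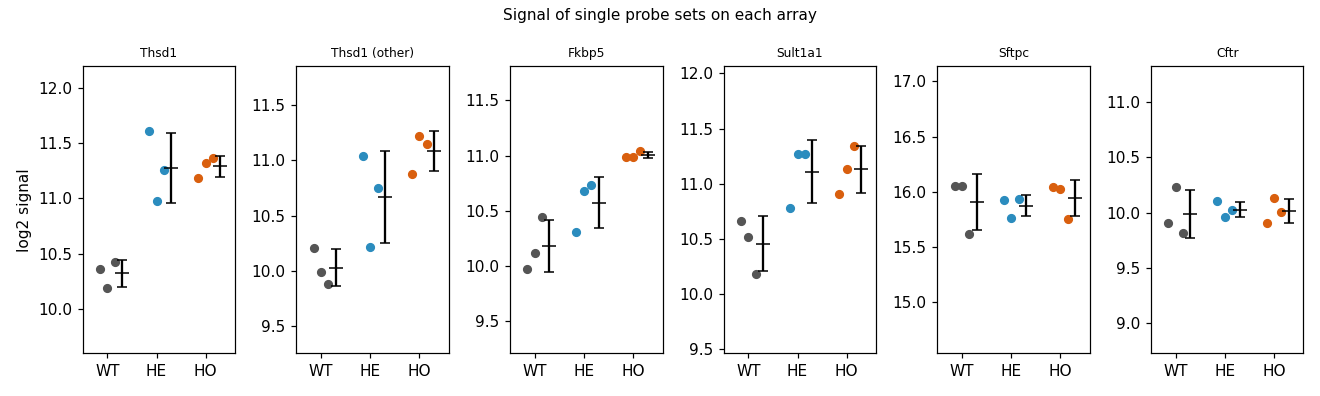
Log2 signal (y axis, each panel spanning the same range) of 6 probe sets on the 9 arrays by genotype group (x axis); points are arrays, and bars give the mean ± SD of 3 arrays. Both Thsd1 probe sets have all 6 transgenic arrays above the mean of the WT arrays (10.32 and 10.03), while Sftpc and Cftr have overlapping groups.

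Among 36 gene lists tested in HO against WT, cytosolic heat shock genes were higher as a group: 15 of 18 measured members were higher, with a median log2 difference of 0.26. By array the list median relative to the WT mean was 0.36, 0.18 and 0.05 in HO replicates 1, 2 and 3, and -0.22, -0.03 and 0.27 in the WT replicates, so WT replicate 3 lay above HO replicates 2 and 3. HO replicates 1 and 2 also had the highest 3' to 5' ratios of the 9 arrays (1.354 and 1.388 for Actb). The largest values among the members of lowest p were those of Hsph1 (0.67 ± 0.33), Dnaja1 (0.49 ± 0.19, other probe set 0.08), Bag3 (0.46 ± 0.27) and Hspb1 (0.35 ± 0.19). No heat shock gene passed the test over all genes or adjusted over the list alone (0 in both, with 1 at an unadjusted p under 0.05). The group passed limma's camera test with a preset correlation (adjusted p = 0.00393) but had adjusted p = 0.969 with an estimated correlation. The call was lost without HO replicate 1 (adjusted p = 0.144) and without WT replicate 1 (adjusted p = 0.279). Glucocorticoid-responsive genes in HO had 9 of 16 members higher and a median of 0.09, and did not pass camera (adjusted p = 0.0996). Within that list, Fkbp5 (adjusted p = 0.0043 in limma) and the sulfotransferase Sult1a1 (0.67 ± 0.18, adjusted p = 0.0303 in limma) passed when adjusted over the list alone, and 0 passed over all genes tested. Zbtb16 was at 1.34 ± 0.51 with -0.165 at its other probe set, and did not pass. Immediate early genes had 18 of 20 members lower with a median of -0.17 (adjusted p = 0.0703 by limma's camera), with Fosb at -1.14 ± 0.53 and Klf4 at -0.38 ± 0.16.

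Groups tied to the transgene and its site of expression had medians close to 0 in HO and did not pass. Alveolar type II cell markers had a median of -0.02 over 19 genes, and the lung epithelial transcription factor Nkx2-1 was at -0.49 ± 0.18 without passing over all genes or over the list alone. Epithelial ion channels and transporters had a median of 0.03 over 20 genes, with the sodium channel subunit Scnn1g at 0.24 ± 0.13. CFTR-interacting proteins had a median of 0.02 over 34 genes. Endoplasmic reticulum stress genes and chaperones had a median of -0.01 over 28 genes. The adjusted p of these 4 lists lay between 0.556 and 0.927 by limma's camera. Innate host defence genes had a median of -0.06 over 17 genes and a mean of -0.02, while camera pointed upward (adjusted p = 0.927 in limma). Inflammatory cytokines, chemokines and NF-kB targets had 15 of 19 members lower and a median of -0.20, without passing (adjusted p = 0.18 by limma's camera). The 35 lists that did not pass had medians between -0.20 and 0.09.

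The second comparison concerned 1 transgenic allele. No probe set passed in HE against WT with limma (lowest adjusted p = 0.685), and 422 had an unadjusted p under 0.05, of which 161 were higher and 261 lower (206 and 222 with quantile normalization, 241 and 180 with median centring). Thsd1 was at 0.96 ± 0.16 on the log2 scale (SE, n = 3 per group) and at 0.64 by its other probe set. Efnb2, the ephrin B2 ligand, was at 0.89 ± 0.20, and Rasd2, a small GTP-binding protein, at -0.996 ± 0.162, with other probe sets nearer 0 (0.32, 0.02 and 0.42 for Efnb2, -0.25 for Rasd2). Vps53, of endosome-to-Golgi transport, was at -0.79 ± 0.14 and mitochondrial thioredoxin Txn2 at -0.74 ± 0.15, while other probe sets of these genes gave 0.05 for Vps53 and 0.25 and -0.30 for Txn2. Of the 20 leading genes in HE, 14 had another measured probe set, and again only Thsd1 had one with an unadjusted p under 0.05 in the same direction. The HE and WT arrays did not overlap for 1045 probe sets (7.70%), where chance gives 10%.

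Glucocorticoid-responsive genes were higher as a group in HE: 15 of 16 measured members were higher than in WT, with a median log2 difference of 0.24. By array the list median relative to the WT mean was 0.048, 0.255 and 0.418 in HE replicates 1, 2 and 3. It was -0.135, 0.066 and 0.048 in the WT replicates, so HE replicate 1 lay below WT replicate 2. The members of lowest p were the lipoprotein lipase inhibitor Angptl4 (0.68 ± 0.20), Sult1a1 (0.65 ± 0.18), Tsc22d3 (0.40 ± 0.23) and Fkbp5 (0.40 ± 0.16, other probe set -0.05). The group passed limma's camera test with a preset correlation (adjusted p = 0.000257), and had adjusted p = 0.998 with an estimated correlation. No member passed over all genes or adjusted over the list alone, where the lowest adjusted p in limma was 0.0527, and 3 had an unadjusted p under 0.05. The call was lost without HE replicate 3 (adjusted p = 0.272) and with HO replicate 2, whose labels conflict, counted as HE (0.109). HE replicate 3 also had the highest neutrophil level of all arrays, with a list median of 0.98 above the WT mean. The other groups did not pass in HE. Of those tied to stress, epithelium and inflammation, heat shock genes had a median of 0.08, immediate early genes -0.14, alveolar type II cell markers -0.04, ion channels and transporters 0.04, CFTR-interacting proteins -0.02, endoplasmic reticulum stress genes -0.03, inflammatory genes 0.03, host defence genes 0.01 and neutrophil markers 0.27. The means of ion channels and transporters (-0.01) and host defence genes (-0.03) had the opposite sign to their medians. The members of these 9 groups at an unadjusted p under 0.05 in HE were the chloride channel Ano1 (-0.43 ± 0.18), the anion exchanger Slc26a6 (-0.32 ± 0.14), Edem1 of endoplasmic reticulum degradation (-0.35 ± 0.13, other probe set -0.015) and the chaperone Hyou1 (0.60 ± 0.25, other probe set -0.42), and these did not pass over all genes or over their lists alone.

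**Figure D2:**
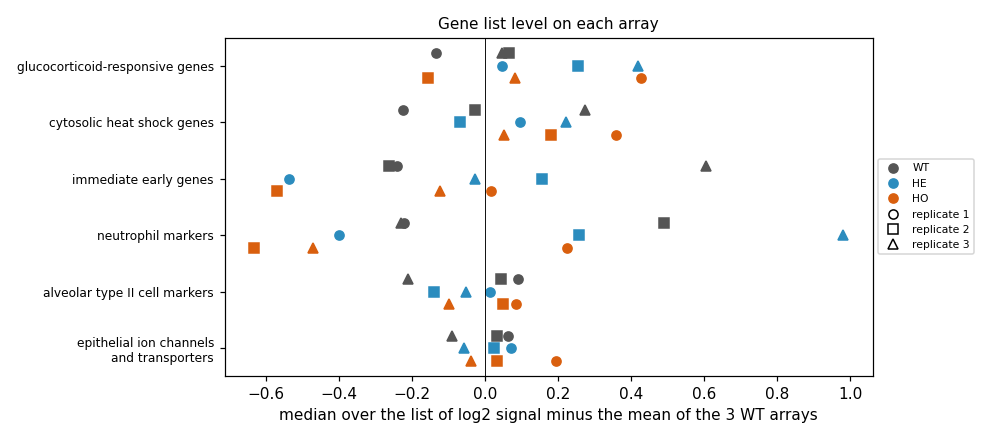
Median over each gene list of the log2 signal minus the mean of the 3 WT arrays (x axis) for 6 lists (y axis); each point is an array, coloured by group and shaped by replicate number. The 3 arrays of a group spread widely within most lists; the HE arrays run from -0.40 to 0.98 for neutrophil markers.

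The third comparison set 2 alleles against 1. No probe set passed in HO against HE with limma (lowest adjusted p = 1), and 348 had an unadjusted p under 0.05, of which 158 were higher and 190 lower in HO (172 and 171 with quantile normalization, 198 and 146 with median centring). Rasd2 (0.76 ± 0.16, other probe set 0.04) and Polr1b, a subunit of RNA polymerase I (0.67 ± 0.15), were at the upper end, and Eipr1 (-0.70 ± 0.15) and Pou2f3, a transcription factor of tuft cells (-1.49 ± 0.33), at the lower end. The groups did not overlap for 904 probe sets (6.66%), again where chance gives 10%. Neutrophil markers were lower in HO as a group, with 7 of 8 members lower and a median of -0.62. Against WT their medians were -0.20 in HO (8 of 8 lower, adjusted p = 0.487 by limma's camera) and 0.27 in HE (6 of 8 higher, adjusted p = 0.428). S100a8 was at -1.23 ± 0.71, S100a9 at -1.25 ± 0.81 and the receptor Csf3r at -1.04 ± 0.60. Inflammatory genes had 14 of 19 members lower with a median of -0.09, with Cebpd at -0.70 ± 0.22 (other probe set -0.15). Heat shock genes had 17 of 18 members higher with a median of 0.15. With a preset correlation these groups passed limma's camera test (adjusted p = 0.0187, 0.0241 and 0.0311 in that order), and each had adjusted p = 0.965 with an estimated correlation. Over all genes, and adjusted over each list alone, 0 members passed. The neutrophil call was lost without HE replicate 3 (adjusted p = 0.617), HO replicate 2 (0.161) or HO replicate 3 (0.227), and with HO replicate 2 counted as HE (0.457). The inflammatory call was lost without HE replicate 2 (0.528), HE replicate 3 (0.137) or HO replicate 3 (0.424). The heat shock call was lost without HE replicate 1 (0.206), HE replicate 2 (0.251), HO replicate 1 (0.574) or HO replicate 3 (0.0608).

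Both transgenic groups were then set together against WT. No probe set passed with limma (lowest adjusted p = 0.362, that of Thsd1), 569 had an unadjusted p under 0.05 (223 higher and 346 lower, but 282 and 274 with quantile normalization and 381 and 195 with median centring), and the F test over the 3 genotypes gave 0 and 420 in the same order. Thsd1 was at 0.96 ± 0.14 on the log2 scale (SE, 6 arrays against 3) and at 0.85 by its other probe set. Sult1a1 was at 0.66 ± 0.16, Fkbp5 at 0.61 ± 0.14 with 0.05 at its other probe set, and Tagln2 at -0.68 ± 0.12, with -0.21 at its other probe set. Glucocorticoid-responsive genes had 12 of 16 members higher with a median of 0.13, heat shock genes 14 of 18 with a median of 0.17, and immediate early genes 18 of 20 lower with a median of -0.23. Relative to the WT mean, the immediate early median was -0.241, -0.262 and 0.606 in WT replicates 1, 2 and 3, and ran from -0.568 to 0.156 on the transgenic arrays. The glucocorticoid median was -0.155 in HO replicate 2, below the WT arrays (-0.135 to 0.066), and 0.048 to 0.426 on the other transgenic arrays. All 3 lists passed limma's camera test with a preset correlation (adjusted p = 0.00315, 0.0452 and 0.0452 in that order), and each had adjusted p = 0.979 with an estimated correlation. Of the 84 ways to set 6 arrays against 3, 27 gave as small a camera p for heat shock genes and 35 for immediate early genes. These splits can also take in differences between replicate numbers, over which genotype is balanced. The counts thus cannot decide, and chance is not excluded. In the glucocorticoid list 2 genes, Fkbp5 and Sult1a1, passed when adjusted over the list alone (adjusted p = 0.0127 for both in limma), against 0 over all genes. Its call was lost without HE replicate 3 (0.0594), HO replicate 1 (0.171) or WT replicate 1 (0.0857). The heat shock call was lost without any of HE replicate 1 (0.0564), HE replicate 3 (0.282), HO replicate 1 (0.234), WT replicate 1 (0.901) or WT replicate 2 (0.171). The immediate early call was lost without any of HE replicate 1 (0.502), HE replicate 3 (0.0594), HO replicate 2 (0.312), HO replicate 3 (0.0794) or WT replicate 3 (0.844).

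The HO and HE differences from WT were set side by side, with the WT arrays that they share. At an unadjusted p under 0.05, 54 probe sets were higher and 72 lower in both, and 1 went opposite ways. Simulated arrays with no effect and no link by replicate number, with 3 WT arrays shared by both comparisons, gave means of 86.3 higher (range 56 to 107) and 86.4 lower (61 to 118), and independent lists would share 2.72 and 7.32. Across probe sets, which are not independent replicates, the differences correlated at 0.559 against 0.502 in the simulations (0.470 to 0.542), and their covariance was 0.0201 against 0.0210 (0.0192 to 0.0234). The share of the same sign was 69.3% against 66.7% (65.8% to 67.9%). This share and the correlation lay above the simulated range, the count higher in both groups lay below it, and the count lower in both and the covariance lay within it. Of the 108 ways to relabel the arrays within replicate numbers, a check chosen after seeing the data, 100 were drawn; 27 gave as high a correlation and 23 as high a share, so neither is set apart from chance. They gave 54 or more higher in both in 43 and 72 or more lower in both in 12. With 3 WT arrays a split would leave a single array in 1 part, so the controls were not split. Sharing them gave a correlation of 0.502 in the simulations with no effect, so most of the observed 0.559 needs no effect of the transgene.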

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

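The 3 gene lists named here were singled out because a test of HO against HE itself placed the effect of 2 alleles apart from that of 1. Cytosolic heat shock genes had a median log2 difference of 0.149 between HO and HE (17 of 18 genes higher, adjusted p = 0.0311 by limma's camera with a preset correlation and adjusted p = 0.965 with an estimated correlation). Inflammatory cytokines, chemokines and NF-kB targets had a median of -0.092 (14 of 19 lower, adjusted p = 0.0241 by limma's camera with a preset correlation and adjusted p = 0.965 with an estimated correlation).

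Neutrophil markers had a median of -0.617 between HO and HE (7 of 8 lower, adjusted p = 0.0187 by limma's camera with a preset correlation and adjusted p = 0.965 with an estimated correlation). Among the 10 ways to part these 6 arrays into 3 and 3, 2 gave as small a p for this list, 0.00052 in the real split and 5.62e-11 at the smallest of the others; 10 splits are too few for a share under 0.05. A single array may carry much of the difference: without HE replicate 3, whose list median lay 0.98 above the WT mean, the median was -0.239. The other HE arrays lay at -0.40 and 0.26, the HO arrays at 0.22, -0.63 and -0.47 and the WT arrays at -0.22, 0.49 and -0.23, so the range within each group was wider than the difference. An effect of genotype stays open and was not tested apart from these.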

How the results depend on the processing

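Counting HO replicate 2 as HE was chosen after seeing the data; all other settings were fixed before. The count of probe sets past limma's adjusted p of 0.05 was 0 in every comparison under all settings except the following. Without a filter it was 2 in HE against WT, 2 in HO against HE and 2 in the F test (Fezf2 and Syt8, both under the filter otherwise). With an array left out it ranged from 0 to 1 in HO against WT, HE against WT, both groups against WT, the F test and the overlap of calls; the 1 was Slurp1, without WT replicate 1. Probe sets at an unadjusted p under 0.05 ranged over the settings from 369 to 1225 in HO against WT, 260 to 992 in HE against WT, 215 to 783 in HO against HE and 352 to 1191 in both groups against WT, with the upper ends reached without a filter, where more probe sets were tested. Without HO replicate 3 it was 1001 in HO against WT and 661 in HO against HE, without HO replicate 2 397 in HO against WT, and without HE replicate 1 527 in HO against HE.

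With the replicate block the count of probe sets was 0 in every comparison, and every list called stayed called. The lists called in HO against HE went from 3 to 5 with oxidative phosphorylation and ribosomal protein genes (adjusted p = 0.0414 for both by limma's camera, 0.947 with an estimated correlation), and no other call changed. The numbers did not pair HE with WT (r = 0.30, 0.05 and 0.04) or HO with HE (0.16, 0.15 and 0.03) by the fixed criterion. These r were all positive, while arrays of different groups and numbers had a median r of -0.095. Further, 8 of 9 arrays correlated best with an array of their own number, so a link of HE to the numbers is not excluded.

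The number of lists called by camera was 0 in every comparison with an estimated correlation and with fry. It was 2 in HO against WT with quantile normalization, 2 in HE against WT without a filter, and 2 in HO against WT and 6 in HO against HE with HO replicate 2 as HE. With an array left out it ranged from 1 to 5 in HO against WT, 0 to 7 in HE against WT, 0 to 7 in HO against HE and 0 to 5 in both groups against WT. Adjusted p of the called lists in limma was 0.969, 0.998, 0.965 and 0.979 with an estimated correlation, in the order of the comparisons HO with WT, HE with WT, HO with HE and both with WT, and 0.982, 0.991, 0.959 and 0.981 with fry. Other adjusted p above 0.05, from limma's camera, were these. For heat shock genes, HO against HE gave 0.106 and both groups against WT 0.332 with quantile normalization, and 0.0604 and 0.0535 without a filter. Without a filter, inflammatory genes in HO against HE gave 0.436 and immediate early genes in both groups 0.292. With HO replicate 2 as HE, glucocorticoid genes in HE against WT gave 0.109, neutrophil markers 0.457 and immediate early genes 0.137.

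With an array left out, adjusted p by limma's camera ranged for heat shock genes from 1e-06 to 0.279 in HO against WT, 0.00297 to 0.574 in HO against HE and 2.55e-05 to 0.901 in both groups. For glucocorticoid genes it ranged from 1.44e-05 to 0.272 in HE and 2.02e-06 to 0.171 in both groups, for immediate early genes from 0.000472 to 0.844, for inflammatory genes from 0.000146 to 0.528 and for neutrophil markers from 3.97e-05 to 0.617. The causes were not tested.

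For the named genes, 3228 of 3262 values under alternatives kept their direction and 34 did not, 23 of these with an array left out; none of the genes passed. No setting moved the median of all probe sets by over 0.1. The values that changed sign were near 0 or varied within groups. Sftpc was at -0.025 in HO against WT and -0.012 in HO against HE with quantile normalization, 0.001 in HE against WT and 0.044 in both groups with median centring, and 0.006 in both groups with array weights. Cftr in HO against HE was at 0.003 with median centring. With HO replicate 2 as HE, Sftpc was at -0.009, 0.002 and -0.011 in HO against WT, HE against WT and HO against HE, Cftr at -0.028 in HO against WT and Ptgs2 at 0.007 in HO against HE. With an array left out, Sftpc ranged from -0.114 to 0.127 in HO against WT, -0.182 to 0.038 in HE against WT and -0.148 to 0.072 in both groups. Cftr ranged from -0.054 to 0.151, -0.04 to 0.165 and -0.047 to 0.158 in the same order, and from -0.071 to 0.04 in HO against HE. In HO against WT, Retnla ranged from -0.186 to 0.634, S100a8 from -1.054 to 0.238 and S100a9 from -1.058 to 0.374. In HE against WT, Lyz2 ranged from -0.033 to 0.222 and Mmp8 from -0.094 to 0.953.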

Other observations

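The tests of the time of day, of the other Thsd1 probe set and of the 27 splits were chosen only after the results they bear on were seen, and the 3 genes of the next paragraph were picked after their values were seen. The other tests of Thsd1, of the glucocorticoid list and of the neutrophil list concern patterns found in these same data, so those patterns were seen before the tests were chosen.

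Slurp1, a secreted epithelial protein of the Ly6 family, had log2 signals of 9.64 to 10.03 on the HO arrays and 8.86 to 9.65 on the HE arrays. WT replicates 2 and 3 were at 6.63 and 7.26, but WT replicate 1 was at 10.12. Without that array Slurp1 was 2.84 ± 0.26 (SE) higher in HO and 2.35 ± 0.26 higher in HE (adjusted p = 0.00626 and 0.0368 in limma), while with all arrays the differences were 1.78 ± 0.67 and 1.29 ± 0.67, and the adjusted p without any other array ranged from 0.673 to 1. Among probe sets under the filter, Fezf2 lay at or near the floor on the WT and HO arrays (4.67 to 4.96) and at 6.67 to 7.32 in HE. Syt8 was at 6.87 to 6.97 in HE and at 8.44 to 9.21 on the other arrays. Among the remaining lists, all 7 proliferation genes measured were lower in HE than in WT (median -0.15, adjusted p = 0.323 by limma's camera). In HO against HE, 22 of 24 oxidative phosphorylation genes (median 0.09) and 13 of 14 ribosomal protein genes (median 0.12) were higher. Adjusted p was 0.0543 for both by limma's camera and 0.0414 with the replicate block, but 0.947 with the block and an estimated correlation.

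The replicate number parted the arrays more than genotype did. The F test over the 3 numbers placed 1718 probe sets at an unadjusted p under 0.05 (1 at an adjusted p under 0.05 in limma), against 420 for genotype. Of 100 splits of the 9 arrays into 3 groups of 3, 92 gave at least as many as genotype, the highest being those 1718. Each genotype holds 1 array of each number, while other splits can group arrays of a number and take in that difference. These splits thus cannot decide, and chance is not excluded. Of the 84 ways to set 6 arrays against 3, 45 gave at least as many as the 600 that a 2-group fit gave for WT, with 1636 the highest. Of the 27 splits that set apart 1 array of each replicate number, 6 gave at least 600, and with the number as a block 4 gave at least the real 814, so chance cannot be excluded there either. The 3 splits of the 84 that set 1 replicate number apart gave 1127 to 1636, which points to a structure of the samples. With the replicate number as a block, 0 probe sets passed in any comparison. For 3 arrays against 3, 10 splits are too few for a share under 0.05. HO against WT had 610 probe sets with 1240 the highest other split (6 of 10 as large), HE against WT 422 with 1019 (9 of 10) and HO against HE 348 with 1085 (9 of 10). Of the HO and WT splits, 4 part all 3 pairs of equal number. The real one gave 610 and the others 340 to 608, while the 6 that keep a pair together gave 523 to 1240. In HE against WT the real split gave 422, and the others that part all pairs gave 305, 527 and 619. In HO against HE the real split gave 348, and the others that part all pairs gave 276, 579 and 730. The number of lists called by camera in both groups against WT, 3, was reached by 75 of the 84 splits, whose median was 7. Among the 27 splits 20 reached it, with a median of 4, and 23 did with the number as a block. For 3 arrays against 3, the real split called 1 list in HO against WT and 1 in HE against WT, where the other splits called 2 to 17. In HO against HE it called 3, and the others 1 to 12. For heat shock genes in HO against WT the real split had a camera p of 0.000109. Other splits gave smaller ones of 3.89e-05, 1.32e-08 and 2.87e-09. In HO against HE the real camera p was 0.00259, and other splits gave smaller ones of 0.000298 and 0.000314.

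Glucocorticoid-responsive genes, higher in the transgenic groups by limma's camera with a preset correlation but at adjusted p = 0.979 with an estimated one, could be a chance feature of these arrays. Of 84 splits of 6 against 3, 13 gave as small a p for the list. It was 0.000144 in the real split and 1.96e-10 at the smallest of the others. Of the 27 splits, 6 gave as small a p, with or without the number as a block. In HE against WT the real split had the smallest camera p of the 10 splits, 7.13e-06, with 0.000132 next. In HO against WT the real p was 0.0083 and the smallest of the others 1.09e-08. For either comparison 10 splits are too few for a share under 0.05. Whether the shift in both groups rests on a few members stays open: the 12 left without the 4 of lowest p had a median of 0.04, with 8 of them higher, but those 4 were chosen by their p, so the median had to fall. The time of day at which lungs were taken stays open: clock genes gave an unadjusted p of 0.804 by limma's fry rotation test for change in either direction, but the 95% intervals of 8 of 12 reached a log2 difference of 0.5. An effect of genotype stays open as well.

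Thsd1 was the gene of lowest p in the transgenic groups, and 8 of 84 splits gave some probe set a p as small, 1.07e-05 in the real split and 1.19e-07 at the smallest of the others. Of the 27 splits 1, the real one, reached that p, a share under 0.05 that goes against chance. However, the smallest p of the others was close to it at 1.38e-05. With the number as a block 6 of 27 gave a p as small as the real 1.87e-05, so chance cannot be excluded. A fault of 1 probe set alone is argued against by the other Thsd1 probe set, 0.848 higher on the log2 scale with a 95% interval of 0.47 to 1.23. The 10 nearest measured genes on chromosome 8 had a mean absolute log2 difference of 0.189, at percentile 95.7 of 7968 windows of 10 genes, with 4 higher and 6 lower (Slc20a2 at -0.36, Mrps31 at -0.28 and Vps36 at 0.25 among them). This percentile met the prediction set for an altered stretch of chromosome around Thsd1. However, the measure does not scale for the noise of each gene and the neighbours moved both ways, so it cannot settle that explanation. A response to the transgene stays open as well.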
